A study of Mus musculus with 8 samples.

How the data were processed

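Single-nucleus RNA was measured in ventricular nuclei of ICR/CD1 mice given permanent ligation of the left anterior descending artery (myocardial infarction, MI) or sham surgery at postnatal day 1 (P1) or postnatal day 8 (P8), collected 1 or 3 days later. Nuclei were sorted for PCM1, a protein of the cardiomyocyte nuclear membrane, before droplet capture with 10x 3' version 2 chemistry. The series holds 8 libraries, 1 for each combination of age, day and surgery. The labels do not state how many animals gave each library, so p-values here measure only the spread between these libraries, and no single condition could be tested against another.

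Per the submitters' processing notes, Cell Ranger and Seurat were used with the mm10 genome (GRCm38); versions, alignment settings and filters are not given in the sources used here. Each deposited count matrix holds UMI counts per gene and barcode for barcodes already called as nuclei. The deposited cardiomyocyte table holds natural log values; each of 16885120 values compared (632858 above 0) matched the log-normalised counts of the same barcode within a tolerance of 1e-09, and 30152 of 31586 barcodes (95.46%) are in that table. These 30152 barcodes are called table nuclei below. A separate deposited table of sham nuclei alone was not used here. Counts, not log values, entered every test. The matrices hold 27998 genes; genes were kept by Ensembl ID, and GENCODE M21 served for gene lengths and coordinates (GRCm38) alone, with 27645 of 27998 IDs found (98.7%).

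For the main comparisons, counts of table nuclei were summed per library. Genes passed the expression filter of edgeR 4.0.16, scaling was TMM, and quasi-likelihood F tests used limma 3.58.1 and R 4.3.3 with Benjamini-Hochberg adjusted p of at most 0.05 as the threshold. The comparisons, lists, tests, named-gene rule and other settings, except those given as added, were fixed before the data were examined. MI was compared with sham over 4 matched pairs (same age and day) with the pair as a block, then within P1 and within P8 surgery. The P8 effect was compared with the P1 effect, the day 3 effect with the day 1 effect, and P8 sham with P1 sham. These fits leave 2 residual degrees of freedom for the comparisons within or between ages and days and 3 for sham age. No library repeats another, so the spread is not that of replicates. Over 4 pairs it is the disagreement of the MI effect between pairs, with age and day included. Within or between ages it is the disagreement between day 1 and day 3, pooled over both ages. For the day comparison it is the disagreement between P1 and P8. DESeq2 1.42.0 was the alternative test. On simulated counts with no effect and 100 genes each changed 2-fold and 4-fold, the table nuclei design recovered 24% and 86% of them for MI over 4 pairs, 3% and 58% within P1, and 4% and 51% within P8. The simulated spread came from the fit with a single MI effect for all pairs. Differences between the P1 and P8 effects thus entered it as spread.

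There were 24 gene lists and 15 marker lists of cell types, written beforehand. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry; list p-values were adjusted over the lists of each comparison. A nucleus counted as holding G2M transcripts when UMIs of at least 2 of 51 measured G2M genes were seen after thinning it to 1000 UMIs; nuclei with fewer UMIs were left out. Differences in that share were tested with an exact sign flip over 4 pairs, whose smallest possible p rounds to 0.13. Intervals of shares are exact binomial 95% intervals and hold counting error alone. Single pairs are given as ratios of normalised counts (CPM) with exact 95% intervals; they need at least 50 UMIs over the pair and have no test between animals. For a gene with 0 UMIs in sham the exact 95% lower limit of the ratio is given.

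Cell classes were assigned after the data were seen. All 31497 barcodes with at least 200 genes were clustered in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2) on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1.0. A cluster was named for another cell type when at least 3 markers and at least 50% of that type's detected markers stood 4-fold above the median cluster. Cardiomyocyte-like clusters had at least 5 cardiomyocyte markers above their mean in the other types and were neither mixed nor rich in mitochondrial RNA. The mixed cluster was moved out of the cardiomyocyte-like set after it was seen to change the P1 count, and counts with and without it are given. The doublet caller marked 13 of 31497 barcodes (0.0413%), too few to be a usable call, so no doublets were removed; leaving out the highest doublet scores was an added alternative. The cardiomyocyte-like results use the same fits and repeat each comparison, and were chosen after seeing the data.

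Named genes were the 8 with the largest rises and the 8 with the largest falls among those past the threshold, with a mean of at least 20 CPM in an arm and the same sign in each pair (no overlap of groups for comparisons between effects and ages), excluding predicted and clone-named genes. Where fewer than 3 passed, the 5 with the smallest p were named and are described as not passing. Up to 4 list members past the threshold, by p, and a fixed set of contractile, stress, cell cycle, NF-Y and Nfe2l1 genes were named as well. A few genes that meet this rule are not reported here. Values are log2 changes with an approximate standard error (SE), the absolute log2 change divided by the square root of its F statistic.

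Median depth per table nucleus ran from 1067 UMIs and 702 genes (P8 sham day 3) to 2884.5 UMIs and 1512 genes (P1 MI day 3). Library totals ran from 4662621 to 10001015 UMIs, and the precision this gives is in the SE or interval printed with each value. Other settings were RLE scaling, no count filter, at least 50 counts in at least 4 libraries, DESeq2, every barcode of the matrices, equal nuclei and thinned totals, leaving out mitochondrial, ribosomal protein and haemoglobin genes with Malat1, leaving out each library, additive age and day in place of the pair, and sham libraries alone for age. Added after seeing the data were the cardiomyocyte-like set and its variants, the tests in other cell classes, and fry. Correlations across genes used log2 ratios of CPM with 2 CPM added, set against 50 simulated sets with no effect. Figures were drawn with matplotlib 3.10.9.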

Results

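After the PCM1 sort, the nuclei of the deposited cardiomyocyte table fell into cardiac muscle and other classes. Of 30152 table nuclei, 17326 (57.5%) lay in clusters with cardiomyocyte markers alone, called cardiomyocyte-like here. A further 8396 (27.8%) lay in clusters with markers of other cell types, among them 3637 fibroblast-like (12.1%), 1424 macrophage-like (4.72%) and 1405 endothelial-like nuclei (4.66%). Clusters rich in mitochondrial RNA held 2863 (9.50%), and a cluster called mixed here held 1567 (5.2%). In the mixed cluster, 8 of 9 cardiomyocyte markers stood above their mean in the other types. Of other markers, 4 endothelial, 1 mural, 1 epicardial and 4 atrial ones stood 4-fold above the median cluster. For fibroblast and macrophage markers this number was 0. The top 10 genes of the mixed cluster were Nppa, Clu, Acta1, Myl4, Hspb1, Mif, Myl7, Acta2, Des and Actc1. Of these, Nppa, Myl4 and Myl7 are on the atrial list. Acta1, Acta2, Actc1, Myl4 and Myl7 are on the immature contractile list, and Nppa, Acta1, Hspb1 and Des on the stress and hypertrophy list. The cardiomyocyte-like share, without the mixed and mitochondrial RNA-rich clusters, was lower in P1 than in P8 libraries. Mitochondrial RNA-rich clusters 1 and 2 had 9 and 6 of 9 cardiomyocyte markers above the other types. The macrophage-like cluster had 9 of 9 too, so this does not settle their class. Counting these and the mixed cluster as cardiomyocyte-like would put P1 MI above P8 MI day 3. Mitochondrial RNA-rich and mixed clusters held 10.4% and 24.3% of P1 MI day 3, against 0.954% and 0.975% of P8 MI day 3. At day 1 after P1 surgery the cardiomyocyte-like share was 35.2% [95% interval 33.5 to 36.9] in MI and 23.1% [21.5 to 24.8] in sham. At day 3 it was 41.5% [39.6 to 43.5] in MI and 38.1% [36.8 to 39.3] in sham. After P8 surgery it was 82.9% [81.7 to 84.2] in MI and 86.6% [85.6 to 87.6] in sham at day 1. By day 3 it was 51.8% [50.4 to 53.2] in MI and 88.8% [87.8 to 89.8] in sham. Fibroblast-like nuclei were 6.88% [6.01 to 7.84] of P1 MI day 1 against 24.6% [22.9 to 26.2] of its sham, and 18.5% [17.4 to 19.6] of P8 MI day 3 against 5.02% of its sham. Macrophage-like nuclei were 11% [10 to 12] of P8 MI day 3 and 1.27% [0.937 to 1.68] of its sham. At P1 their share was lower in MI than in sham, 4.55% [3.84 to 5.36] against 8.46% [7.43 to 9.58] at day 1 and 2.97% [2.34 to 3.70] against 4.59% [4.06 to 5.18] at day 3. The mixed cluster held 27.3% [25.7 to 28.9] of P1 MI day 1 and 24.3% [22.7 to 26.0] of P1 MI day 3, against 1.87% and 0.18% of their shams and at most 0.975% of a P8 library. Shares of classes were not tested between conditions. The intervals hold counting error alone, and the sort itself can set these shares.

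**Figure D1:**
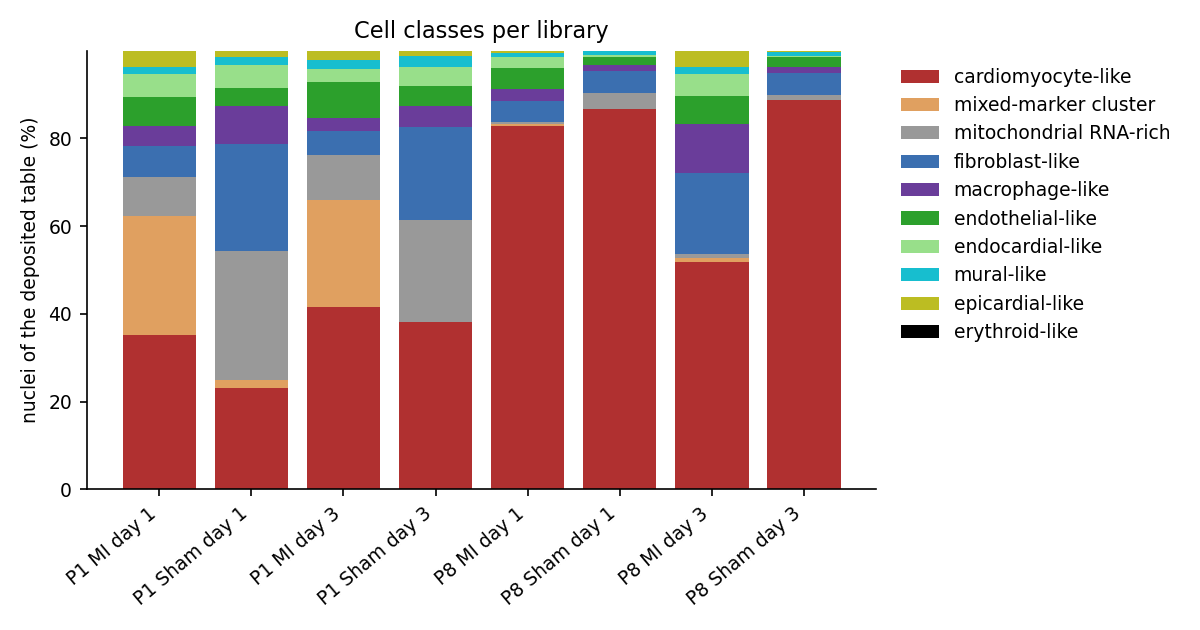
Share of table nuclei in each class, per library, in percent. Cardiomyocyte-like nuclei made up 23.1% (P1 sham day 1) to 88.8% (P8 sham day 3) of a library.

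RNA quality also differed by condition. Mitochondrial transcripts took 23.9% and 18.8% of UMIs in P1 sham at day 1 and day 3, against 6.89% and 6.92% in P1 MI. At P8 they took 4.07% and 3.59% in sham and 4.60% and 6.79% in MI. Clusters rich in mitochondrial RNA held 29.3% and 23.2% of P1 sham nuclei and 8.88% and 10.4% of P1 MI nuclei. Among cardiomyocyte-like nuclei, cluster 6 held most of those in both P1 sham libraries (522 and 1635) and in P1 MI day 3 (564). Clusters 5 and 6 held most of P1 MI day 1 (497 and 472), and clusters 10 and 5 most of P8 MI (1201 and 1066 at day 1, 1905 and 307 at day 3). Cluster 14 held most of P8 sham (2227 and 2408). Cardiac transcripts were present in other classes too: the median cardiomyocyte marker stood at 32.5%, 40.8% and 46.0% of its cardiomyocyte-like CPM in fibroblast-like, macrophage-like and endothelial-like nuclei.

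Over the 4 matched pairs, Xirp2, which encodes an actin-binding protein of the intercalated disc, and the atrial natriuretic peptide gene Nppa rose most clearly in cardiomyocyte-like nuclei after MI. Xirp2 rose by 3.73 log2 (SE 0.18, adjusted p = 2.62e-05, n = 4 pairs), a fitted 13.2-fold, with means of 110.2 CPM in sham and 1335 CPM in MI, and was higher in MI in 4 of 4 pairs. Nppa rose by 3.18 (SE 0.19, adjusted p = 8.26e-05) and the hyaluronan receptor gene Cd44 by 3.52 (SE 0.43, adjusted p = 0.00283), each in 4 of 4 pairs. Spp1 (osteopontin, 3.89, SE 0.96, adjusted p = 0.0239) and Eno2 (an enolase of glycolysis, 3.73, SE 0.59, adjusted p = 0.00574) rose as well. So did Ndrg1 (3.18, SE 0.39), P3h2 (3.15, SE 0.34) and Tpm2 (beta tropomyosin, 2.83, SE 0.32), these 3 at adjusted p = 0.00283. Falls were led by Caln1 (-2.44, SE 0.48, adjusted p = 0.0116), Plcd4 (-1.88, SE 0.30), Retsat (retinol saturase, -1.88, SE 0.22, adjusted p = 0.00283) and Sat2 (-1.85). Cd1d1 (-1.77), Dhrs7 (-1.75) and Mroh5 (-1.69) fell too. Among the fixed genes, Ankrd1 rose by 1.37 (SE 0.25, adjusted p = 0.00930) and Nppb by 1.15 (SE 0.28, adjusted p = 0.0219, higher in 3 of 4 pairs). The slow and cardiac troponin I genes Tnni1 and Tnni3 fell by 1.07 and 0.73 on the log2 scale (adjusted p = 0.00782 and 0.0151). Myosin heavy chains Myh6 (-0.13, adjusted p = 0.613) and Myh7 (-0.09, adjusted p = 0.654) did not pass. Nor did the cycling genes Mki67 (0.23, SE 0.21, adjusted p = 0.467) and Top2a (-0.16, adjusted p = 0.639). The NF-Y genes Nfya (0.18, adjusted p = 0.617), Nfyb (0.24, adjusted p = 0.555) and Nfyc (-0.17, adjusted p = 0.394), and Nfe2l1 (0.49, SE 0.19, adjusted p = 0.0965) did not pass.

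The gene groups moved as follows in cardiomyocyte-like nuclei. Of 77 nuclear genes of oxidative phosphorylation, 0 rose, 64 fell and 13 did not pass, with 73 lower when adjusted over the list alone. Examples are Ndufa1 (-1.08, SE 0.13), Ndufa5 (-1.09, SE 0.14), Cox7a1 (-1.29, SE 0.16) and Cox6a2 (-1.05). The list test gave adjusted p = 2.83e-31 at the preset correlation and adjusted p = 0.759 with an estimated correlation, which also applies to the next 5 lists. Of 38 genes of fatty acid oxidation, 15 fell (Eci1 -1.22, Fabp3 -1.12, Plin5 -1.14, Acot2 -1.11) and 23 did not pass, with 20 lower adjusted over the list alone (adjusted p = 1.51e-06). Of 35 stress and hypertrophy genes, 22 rose (Xirp2, Nppa, Enah 1.71, Tgm2 1.74), 1 fell and 12 did not pass, with 23 higher and 1 lower adjusted over the list alone (adjusted p = 1.04e-09). Of 23 YAP and TEAD targets, 8 rose (Tgfb2 1.86, Crim1 1.38, Amotl1 1.48) and 15 did not pass, with 13 higher adjusted over the list alone (adjusted p = 1.05e-04). Of 28 hypoxia genes, 9 rose (Ndrg1, Bhlhe40 1.41, Vegfa 1.15, Hif1a 0.69) and 19 did not pass, with 12 higher and 1 lower adjusted over the list alone (adjusted p = 6.64e-04). Of 20 gp130 and STAT3 genes, 8 rose (Timp1 2.58, Osmr 2.18, Socs3 2.20), 2 fell (among them Socs2, -1.13) and 10 did not pass, with 9 higher and 3 lower adjusted over the list alone (adjusted p = 0.00361). Of 28 glycolysis genes, 5 rose and 6 fell (8 and 9 adjusted over the list alone). Their median was -0.11, their mean 0.01 and the list test lower, at adjusted p = 0.631. Pfkp rose by 1.47, while Eno3, Ldhb and Pgam2, muscle and oxidative-tissue forms of their enzymes, fell by 1.06, 0.97 and 0.91 on the log2 scale. Of 19 immature contractile genes, 8 rose, among them Tpm2, Acta1 (2.08) and Cnn1 (3.48). Tnni1, the troponin I of the fetal heart, fell (8 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0663). Of 51 G2M genes, 0 passed over all genes in edgeR and 0 adjusted over the list alone (median 0.01; list adjusted p = 0.618, and adjusted p = 0.922 with an estimated correlation). Beside these groups, 1 of 11 macrophage markers rose (Ptprc, 2.27, SE 0.59, adjusted p = 0.0289) and 0 of 12 fibroblast markers passed.

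In cardiomyocyte-like nuclei, edgeR called 2539 of 13576 genes over the 4 pairs, 1317 higher and 1222 lower after MI. Leaving out P1 MI day 1 or P1 sham day 1 gave 1130 and 1135 calls, leaving out P8 MI day 1 or P8 sham day 1 gave 377 and 389, and leaving out P8 MI day 3 or P8 sham day 3 gave 1590 and 1671. In table nuclei, where other cell types differ in share between arms, edgeR called 9 of 15853 genes, each higher (3375 genes had unadjusted p under 0.05), and DESeq2 called 914 (543 higher, 371 lower). Among the 9 are Xirp2 (3.48, adjusted p = 0.0288), Nes (2.61, SE 0.22, adjusted p = 0.0142) and Pdgfc (2.17, SE 0.18, adjusted p = 0.0142). Others are Acta1 (2.09, SE 0.21, adjusted p = 0.0290), Tgm2 (1.66, SE 0.16, adjusted p = 0.0288) and Cnn1 (3.43, SE 0.36, adjusted p = 0.0293). Nppa (3.21, SE 0.48, adjusted p = 0.0942) and Cd44 (2.29, SE 0.54, adjusted p = 0.124) did not pass there, and no fall passed (smallest p for Il1rapl2, -1.41, adjusted p = 0.0602). Of 36 stress and hypertrophy genes in table nuclei, 3 rose, with 20 higher adjusted over the list alone. The list had adjusted p = 3.82e-10 (and adjusted p = 0.522 with an estimated correlation). Of the 77 oxidative phosphorylation genes there, 0 passed and 27 were lower adjusted over the list alone. Here the list had adjusted p = 5.78e-22 (and adjusted p = 0.553 with an estimated correlation). With table nuclei, leaving out P1 MI day 1, P1 sham day 1, P1 MI day 3 or P1 sham day 3 left 0 edgeR calls, with 3035, 3065, 2884 and 2876 genes at unadjusted p under 0.05. Leaving out P8 MI day 1 or P8 sham day 1 also left 0, with 1405 and 1398 such genes, and leaving out P8 MI day 3 or P8 sham day 3 gave 207 and 237.

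**Figure D2:**
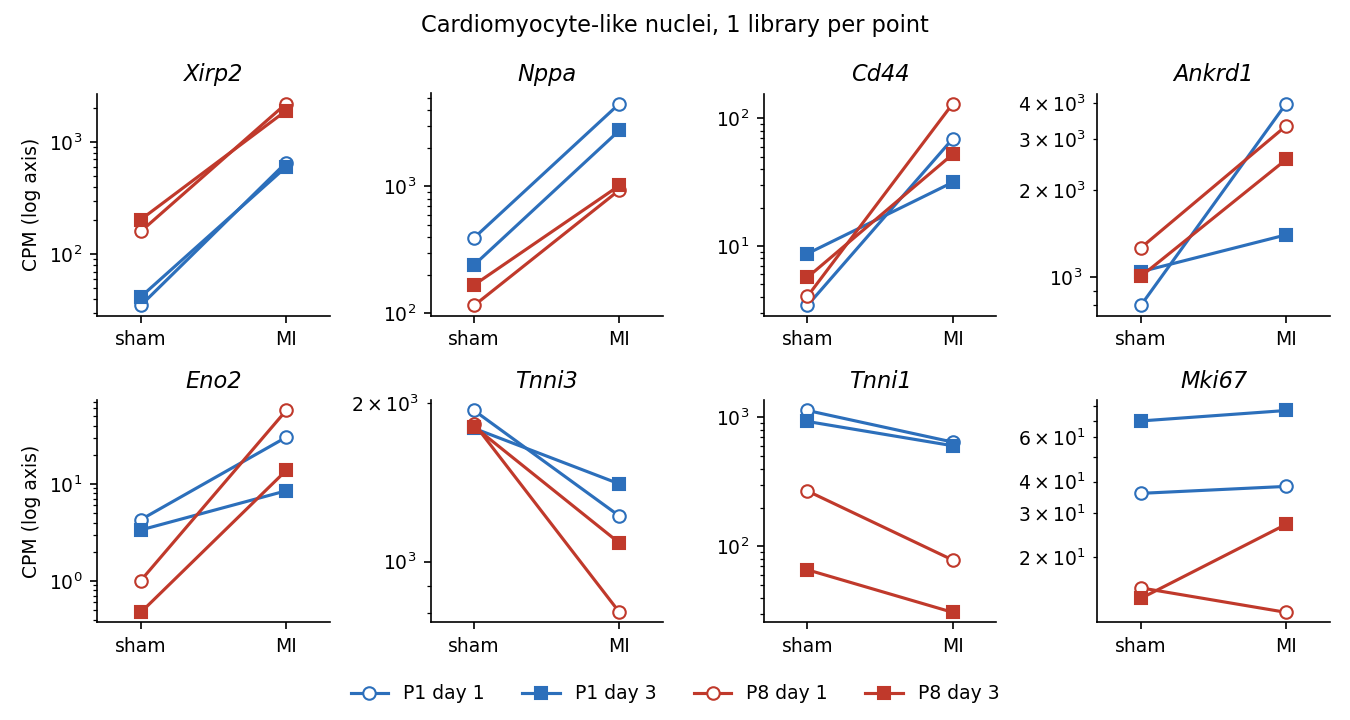
Counts per library (CPM, log axis) of 8 genes in cardiomyocyte-like nuclei, sham beside MI with lines joining matched pairs. Xirp2 rose by 3.73 log2 over the 4 pairs (adjusted p = 2.62e-05) and Mki67 was at 0.23 (adjusted p = 0.467).

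After P1 surgery, the age at which the mouse heart regenerates, Xirp2 and Nppa were again the clearest rises in cardiomyocyte-like nuclei. Xirp2 rose by 4.01 (SE 0.25, adjusted p = 4.26e-05), from 38.5 to 627 CPM, and Nppa by 3.53 (SE 0.22, adjusted p = 4.26e-05), from 316 to 3653 CPM, both higher in 2 of 2 P1 pairs. Rises followed for Pdgfc, a platelet-derived growth factor (2.48, SE 0.28, adjusted p = 0.00482), Clca3a1 (2.38, SE 0.38) and Kctd8 (2.26, SE 0.26, adjusted p = 0.00482). Next were Tpm2 (2.25, SE 0.38, adjusted p = 0.0467), P3h2 (2.25, SE 0.30, adjusted p = 0.0152) and Lims2 (2.19, SE 0.37, adjusted p = 0.0467). The 7 named falls were Mfap5, a microfibril component of connective tissue (-2.72, SE 0.38, adjusted p = 0.0217), and Meikin (-2.32), with Dcc (-2.01, SE 0.23, adjusted p = 0.00482), Dhrs7 (-1.58), Cd81 (-1.32), Fitm1 (-1.28) and Cmss1 (-1.15). Also past the threshold were Bcl2, an inhibitor of apoptosis (1.75, SE 0.21, adjusted p = 0.00634), Enah (1.37, SE 0.22, adjusted p = 0.0409) and Nrap (1.34, SE 0.23, adjusted p = 0.0467). Cd44 (2.67, SE 0.51, adjusted p = 0.0519), Ankrd1 (1.36, SE 0.37, adjusted p = 0.101) and Nppb (0.77, SE 0.36, adjusted p = 0.262) did not pass. Nor did Tnni1 (-0.72, SE 0.21, adjusted p = 0.114), Tnni3 (-0.51, adjusted p = 0.218), Myh6 (0.15, adjusted p = 0.740) or Myh7 (-0.03, adjusted p = 0.95). The cycling genes Mki67 (0.12, SE 0.29, adjusted p = 0.852) and Top2a (-0.48, SE 0.26, adjusted p = 0.334), and Nfya (0.27, adjusted p = 0.740), Nfyb (0.14, adjusted p = 0.887), Nfyc (-0.07, adjusted p = 0.877) and Nfe2l1 (0.24, SE 0.27, adjusted p = 0.650) did not pass.

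Among the lists at P1, 4 of 35 stress and hypertrophy genes rose and 31 did not pass, with 19 higher and 1 lower adjusted over the list alone (list adjusted p = 4.13e-10). This list, like each P1 list of cardiomyocyte-like nuclei, had adjusted p = 0.772 with an estimated correlation. No oxidative phosphorylation gene passed over all genes (0 of 77 in edgeR), while 61 were lower adjusted over the list alone (median -0.73; list adjusted p = 4.41e-33). No gene of the 13 encoded by mitochondrial DNA passed over all genes (0 in edgeR), and 9 were lower adjusted over the list alone (median -0.86; list adjusted p = 7.20e-10). Beside this, mitochondrial transcripts took 6.89% and 6.92% of UMIs in P1 MI libraries and 23.9% and 18.8% in their shams. Hypoxia genes had 0 calls among 28 and 6 higher adjusted over the list alone (list adjusted p = 2.23e-04). Of 19 immature contractile genes, 1 rose (Tpm2) and 18 did not pass, with 6 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0116). G2M genes had 0 calls over all genes and a list adjusted p = 0.782.

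At P1, edgeR called 35 genes in cardiomyocyte-like nuclei, 26 higher and 9 lower (2666 at unadjusted p under 0.05), and DESeq2 called 212 (121 higher, 91 lower). With the mixed cluster included the count was 1443 (841 higher, 602 lower). Leaving out the P1 libraries in turn gave 125 (MI day 1), 215 (sham day 1), 156 (MI day 3) and 114 calls (sham day 3). For the P8 libraries it gave 481 (MI day 1), 805 (sham day 1), 510 (MI day 3) and 753 calls (sham day 3). In table nuclei, edgeR called 27 genes at P1, 13 higher and 14 lower, and DESeq2 called 167. Rises there were Nppa (4.04, SE 0.43, adjusted p = 0.00673), Xirp2 (3.94, SE 0.39, adjusted p = 0.00668), Cnn1 (3.35, SE 0.41), Nes (2.51, SE 0.30) and Acta1 (2.26, SE 0.27), the last 3 at adjusted p = 0.00925, with Kctd8, Pdgfc and Tpm2. Falls were led by Nov (-3.40, SE 0.38, adjusted p = 0.00854), Clec3b (-3.05), Dlk1 (-2.94, SE 0.36, adjusted p = 0.00925) and Tcf21, a transcription factor of cardiac fibroblasts (-2.93, SE 0.47, adjusted p = 0.0432). Mfap5 (-2.79), Glp2r (-2.79), Hpse2 (-2.77) and Smoc2 (-2.70) fell too. Of 12 fibroblast markers in table nuclei, 1 fell (Tcf21) and 11 did not pass, with 7 lower adjusted over the list alone (list adjusted p = 9.08e-07, and adjusted p = 0.534 with an estimated correlation). Fibroblast-like nuclei were 6.88% and 5.5% of the P1 MI libraries and 24.6% and 21.2% of their shams. Leaving out P1 MI day 1, P1 sham day 1 or P1 sham day 3 gave 51, 2 and 65 calls in table nuclei, and leaving out P8 MI day 1, P8 sham day 1, P8 MI day 3 or P8 sham day 3 gave 1678, 1728, 1364 and 1463.

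After P8 surgery, the age past regeneration, Eno2 and Xirp2 rose and Caln1 and nuclear genes of mitochondrial respiration fell in cardiomyocyte-like nuclei. Eno2 rose by 5.49 (SE 0.47, adjusted p = 2.96e-04), from 0.742 to 35.4 CPM, and Xirp2 by 3.50 (SE 0.23, adjusted p = 7.12e-05), from 181.8 to 2043 CPM, both in 2 of 2 P8 pairs. Spp1 (5.2, SE 1.11, adjusted p = 0.0136), Cd44 (4.12, SE 0.47, adjusted p = 0.00103), Ndrg1 (4.01, SE 0.40, adjusted p = 4.80e-04) and P3h2 (3.95, SE 0.30, adjusted p = 1.33e-04) also rose. So did the matrix gene Thbs1 (3.91, SE 0.68, adjusted p = 0.00619), the chemokine gene Ccl2 (3.69, SE 0.58, adjusted p = 0.00395) and Nmrk2, a nicotinamide riboside kinase (3.64, SE 0.47, adjusted p = 0.00194). Caln1 went from 130.9 to 10.4 CPM (-3.65, SE 0.23, adjusted p = 7.12e-05). Tacr3 (-3.54, SE 0.31), Prss41 (-3.53, SE 0.35), Pla2g10 (-3.19, SE 0.39), Atp2a3 (-2.96), Ttll6 (-2.83) and Cd1d1 (-2.77) fell as well. Nppa rose by 2.82 (SE 0.22, adjusted p = 1.33e-04), Nppb by 1.49 (SE 0.34, adjusted p = 0.0187) and Ankrd1 by 1.37 (SE 0.35, adjusted p = 0.0276). Tnni1 fell by 1.46 on the log2 scale (SE 0.22, adjusted p = 0.00368) and Tnni3 fell by 0.96 (SE 0.21, adjusted p = 0.0155). Myh6 (-0.41, SE 0.22, adjusted p = 0.233), Myh7 (-0.15, adjusted p = 0.651), Mki67 (0.35, SE 0.30, adjusted p = 0.457) and Top2a (0.27, SE 0.30, adjusted p = 0.579) did not pass. The same holds for Nfya (0.12, adjusted p = 0.828), Nfyb (0.33, adjusted p = 0.585), Nfyc (-0.26, adjusted p = 0.387) and Nfe2l1 (0.70, SE 0.24, adjusted p = 0.0759).

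By list at P8, 56 of 77 oxidative phosphorylation genes fell, 0 rose and 21 did not pass, with 69 lower adjusted over the list alone. Among them are Ndufb2 (-1.74, SE 0.23), Atp5j (-1.76), Uqcrb (-1.63) and Cox7a1 (-1.51). The list adjusted p was 1.82e-26, and adjusted p = 0.796 with an estimated correlation, as for each P8 list of cardiomyocyte-like nuclei. Of 38 fatty acid oxidation genes, 16 fell (among them Eci1 -1.52, the uncoupling protein gene Ucp3 -2.19, Plin5 -1.47) and 22 did not pass, with 20 lower adjusted over the list alone (list adjusted p = 4.16e-08). Of 35 stress and hypertrophy genes, 20 rose and 15 did not pass, with 23 higher and 2 lower adjusted over the list alone (list adjusted p = 7.27e-10). YAP and TEAD targets had 10 rises among 23 (Tgfb2 2.18, Crim1 1.52, Axl 1.93, Ctgf 2.34), with 14 higher adjusted over the list alone (list adjusted p = 1.90e-05). Of 20 gp130 and STAT3 genes, 9 rose (Timp1 3.14, Nfkbiz 2.77, Osmr 2.84), 2 fell (among them Socs2, -1.56) and 9 did not pass, with 11 higher and 2 lower adjusted over the list alone (list adjusted p = 4.77e-04). Immediate early genes split: 7 of 25 rose (Fosl2 1.79, Nr4a1 2.39, Ier3 1.5), while Jun, a subunit of AP-1, fell by 1.51 on the log2 scale (SE 0.22, adjusted p = 0.00292). Adjusted over the list alone, 14 were higher and 2 lower (list adjusted p = 8.42e-05). Of 21 insulin-like growth factor and imprinted genes, 7 rose (Peg3 2.44, H19 2.28, Meg3 1.94, Igf2 1.61) and 14 did not pass, with 7 higher adjusted over the list alone (list adjusted p = 8.97e-04). Slc16a3, a lactate transporter (4.90, SE 0.58, adjusted p = 0.00121), the chaperone gene Hspa1a (4.27, SE 0.82, adjusted p = 0.00944) and Hmox1, heme oxygenase (4.10, SE 0.54, adjusted p = 0.00200), rose too. Beside these groups, 1 of 12 fibroblast markers rose (Fbn1, 1.48), 1 of 11 macrophage markers rose (Ptprc, 3.32, SE 0.63, adjusted p = 0.00905) and the mitochondrial gene mt-Nd6 rose by 2.34. G2M genes had 0 calls of 51 in edgeR, over all genes and adjusted over the list alone (list adjusted p = 0.181).

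At P8, edgeR called 1901 genes in cardiomyocyte-like nuclei, 886 higher and 1015 lower. Leaving out P1 sham day 1 or P1 MI day 3 gave 2899 and 2941 calls, leaving out P8 MI day 1 or P8 sham day 1 gave 365 and 492, and DESeq2 called 838. With at least 50 counts in 4 libraries there were 1174 calls, and with equal nuclei and totals 547 (66 at P1). In table nuclei, edgeR called 2459 genes, 1310 higher and 1149 lower, and each left-out library moved that count by less than 1.5 times. Rises there were led by Spp1 (5.23, SE 1.45, adjusted p = 0.0345), Eno2 (5.19, SE 0.43, adjusted p = 3.71e-04), Thbs1 (4.03, SE 0.39) and Ccl6 (4.0, SE 0.41, adjusted p = 8.48e-04). They include the macrophage-rich galectin gene Lgals3 (3.99, SE 0.69, adjusted p = 0.00564), Slc16a3 (3.97), Cemip (3.83) and the matrix gene Col8a1 (3.80, SE 0.46, adjusted p = 0.00134). Falls were led by Caln1 (-3.72), Prss41 (-3.68), Tacr3 (-3.67), Pla2g10 (-3.35), Mrap2 (-2.91), Atp2a3 (-2.81) and Ucp3 (-2.66). Of 51 G2M genes in table nuclei, 12 rose (Kif15 1.58, adjusted p = 0.00725; Ect2 1.33, adjusted p = 0.0198) and 39 did not pass, with 16 higher adjusted over the list alone. The G2M list had adjusted p = 4.68e-07, and adjusted p = 0.638 with an estimated correlation. In the same nuclei, 9 of 12 endothelial markers rose (Cdh5 1.82, Tie1 1.95, Emcn 2.16; 10 adjusted over the list alone; list adjusted p = 4.56e-07). Macrophage markers rose for 2 of 12 (Ptprc 2.82, F13a1 1.46; list adjusted p = 0.00101) and fibroblast markers for 2 of 12 (list adjusted p = 0.0464). The lowest adjusted p of a table nuclei list at P8 was 0.619 with an estimated correlation. At P8 day 3, fibroblast-like nuclei were 18.5% of MI and 5.02% of sham table nuclei, and macrophage-like nuclei 11% and 1.27%. At P8 day 1 these shares were 4.87% and 5.09%, and 2.74% and 1.45%. Endothelial-like nuclei were 4.70% of MI and 1.82% of sham at day 1 and 6.40% and 2.19% at day 3, and endocardial-like nuclei 2.49% and 0.304%, and 4.94% and 0.370%.

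**Figure D3:**
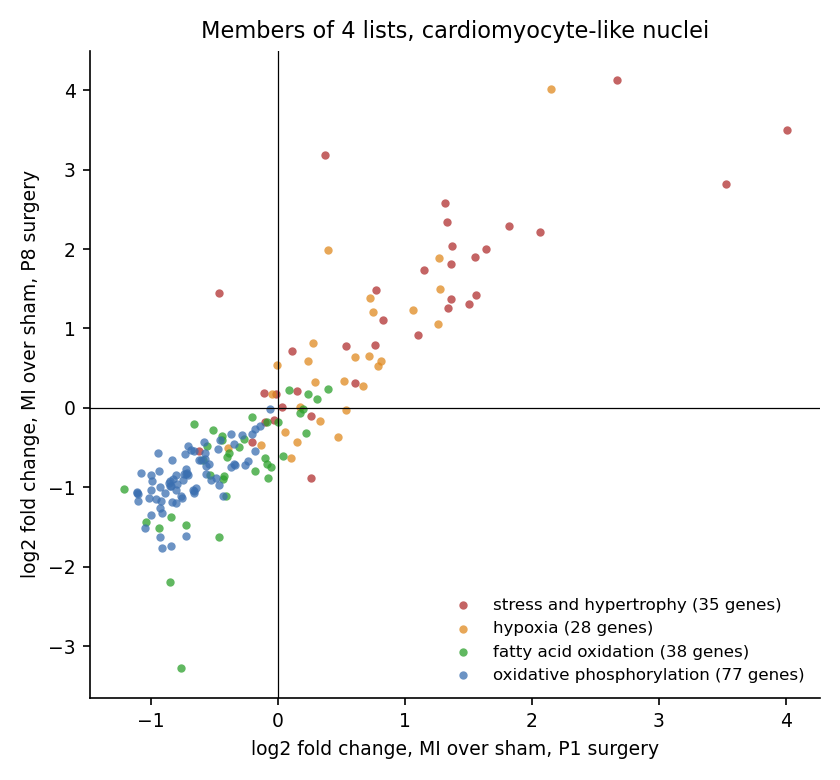
Log2 change after MI at P1 against that at P8, in cardiomyocyte-like nuclei, for the members of 4 lists. Of 77 oxidative phosphorylation genes, 56 fell at P8 and 0 passed at P1, and 0 passed for the difference between ages.

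The MI effect at P8 differed from that at P1 for 12 genes in cardiomyocyte-like nuclei, among them Caln1 and Tacr3, each effect taken against its own shams. The P8 effect on Mfap5 was higher than the P1 effect (3.66, SE 0.49, adjusted p = 0.0264), as were those on Ankrd6 (2.52, SE 0.35, adjusted p = 0.0305) and the receptor phosphatase gene Ptprg (2.33, SE 0.34, adjusted p = 0.0354). Mfap5 is also among the top 10 genes of a fibroblast cluster and fell at P1 in table nuclei (-2.79, SE 0.34, adjusted p = 0.00925), where the fibroblast-like share was lower after MI. Lower at P8 relative to P1 were Tacr3 (-3.38, SE 0.44), the sodium channel gene Scn3a (-3.31, SE 0.39), Mrps27 (-2.74, SE 0.30), Caln1 (-2.72, SE 0.34) and Scaf1 (-2.37, SE 0.29), each at adjusted p = 0.0211, with Tmprss11d (-2.34) and Lrrc48 (-2.11). The 20 CPM minimum was taken over both ages here, so a gene can be low at P1. Caln1 and Scn3a are top 10 genes of clusters 14 and 13. These held 2227 and 2408, and 947 and 641, P8 sham nuclei (day 1, day 3), against 10 and 28, and 28 and 149, in P1 sham. Whether low P1 levels limited a fall there was not tested. For genes past the threshold at P8 and not at P1, the difference itself did not pass for Cd44 (1.46, SE 0.73, adjusted p = 0.663), Ankrd1 (0.01, SE 0.51, adjusted p = 0.998) or Nppb (0.71, SE 0.49, adjusted p = 0.775). It did not pass for Tnni1 (-0.74, SE 0.30, adjusted p = 0.574) or Tnni3 (-0.45, adjusted p = 0.755) either. Xirp2 (-0.51, SE 0.32, adjusted p = 0.737), Nppa (-0.71, SE 0.29, adjusted p = 0.572), Myh6 (-0.56, adjusted p = 0.708), Myh7 (-0.12, adjusted p = 0.954), Mki67 (0.23, SE 0.42, adjusted p = 0.936) and Top2a (0.74, SE 0.40, adjusted p = 0.691) did not pass. Nor did Nfya (-0.14, adjusted p = 0.969), Nfyb (0.19, adjusted p = 0.965), Nfyc (-0.19, adjusted p = 0.926) and Nfe2l1 (0.46, SE 0.36, adjusted p = 0.808). On the simulated counts the age difference recovered 3% of 2-fold and 57% of 4-fold changes in cardiomyocyte-like nuclei. In table nuclei it recovered 0% and 18%, so a gene that did not pass can still differ between ages.

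By list, the difference between ages had few single calls in cardiomyocyte-like nuclei. Over all lists of this comparison, the lowest was adjusted p = 0.686 with an estimated correlation. Genes encoded by mitochondrial DNA were higher at P8 relative to P1 as a list (0 of 13 in edgeR over all genes, 7 adjusted over the list alone; list adjusted p = 1.64e-12), beside mitochondrial UMI shares that were lower in P1 MI than in P1 sham. Oxidative phosphorylation was lower (0 of 77 over all genes and 0 adjusted over the list alone; list adjusted p = 0.0104, and adjusted p = 0.708 with an estimated correlation). The list of 51 G2M genes was higher (0 over all genes and 0 adjusted over the list alone; list adjusted p = 0.0175, and adjusted p = 0.708 with an estimated correlation). Fibroblast and macrophage markers had list adjusted p = 3.21e-05 each, both higher at P8 relative to P1, with 0 calls over all genes and 0 and 1 adjusted over the list alone.

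For the difference between ages, edgeR called 12 genes in cardiomyocyte-like nuclei, 3 higher and 9 lower (1073 at unadjusted p under 0.05), and DESeq2 called 23. Leaving out libraries in turn gave 94 (P1 MI day 1), 159 (P1 sham day 1), 32 (P1 MI day 3), 20 (P1 sham day 3), 100 (P8 MI day 1), 130 (P8 sham day 1), 37 (P8 MI day 3) and 58 calls (P8 sham day 3). Among nuclei under 5% mitochondrial UMIs edgeR called 0 (1027 at unadjusted p under 0.05). In table nuclei, edgeR called 336 genes, 267 higher and 69 lower. This count was 2 with additive age and day in place of the pair, and 81 (64.2% higher, against 79.5%) without mitochondrial, ribosomal and haemoglobin genes and Malat1. Higher were Ccl2 (4.23, SE 0.68, adjusted p = 0.0214), the leukocyte gene Dock2 (4.04, SE 0.57, adjusted p = 0.0154), Thbs1 (3.77, SE 0.49, adjusted p = 0.0142), Ccl6 (3.69, SE 0.53), Spon2 (3.69) and Ptprc (3.68, SE 0.60, adjusted p = 0.0230). So were the mitochondrial genes mt-Nd6 (4.14, SE 0.42, adjusted p = 0.0142) and mt-Atp8 (3.78, SE 0.82, adjusted p = 0.0471). Cd44 differed there (2.60, SE 0.36, adjusted p = 0.0154). Lower in table nuclei were Tacr3 (-3.65), Scn3a (-3.65), Slc35f2 (-3.44), Caln1 (-3.04), Atp2a3 (-3.02), Mrap2 (-2.91), Mrps27 (-2.80) and Tmem104 (-2.72). Of 12 macrophage markers, 1 was higher (Ptprc) and 10 were higher adjusted over the list alone (list adjusted p = 9.43e-11, and adjusted p = 0.558 with an estimated correlation), beside macrophage-like shares that were higher after MI at P8 day 3 and lower at P1. Leaving out P1 MI day 1, P1 sham day 1, P1 MI day 3, P8 MI day 1, P8 sham day 1 or P8 sham day 3 gave 216, 5, 204, 2619, 2645 and 514 calls in table nuclei.

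Across the 13576 genes of cardiomyocyte-like nuclei, the P8 and P1 MI effects, which share no library, had r = 0.568 and rho = 0.572, against a mean r of 0.00125 in simulated sets with no effect; genes are not independent replicates. By day, r was 0.572 at day 1 and 0.284 at day 3. It was 0.440 for P8 day 1 against P1 day 3 and 0.366 for P8 day 3 against P1 day 1. Of the 1901 genes called at P8, 1678 (88.3%) had the same sign at P1, against 71.9% of genes in general. All 26 genes that rose at P1 also rose at P8 (1.70 expected if calls were independent), and 6 of the 9 that fell at P1 fell at P8 (0.673 expected). Both tests come from the same fit and share each gene's variance estimate, so a gene of low variance is favoured in both. The expected numbers do not allow for this.

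Between day 1 and day 3, no gene's MI effect passed, so the following are the smallest p-values and not calls. On the simulated counts this comparison recovered 10% of 2-fold and 57% of 4-fold changes in cardiomyocyte-like nuclei. In table nuclei it recovered 0% and 9%, so such changes can be missed. In cardiomyocyte-like nuclei, Spp1 was higher at day 3 relative to day 1 (5.67, SE 0.91, adjusted p = 0.358), and Cyr61, a YAP target (-2.16, SE 0.32, adjusted p = 0.358), and the prolyl hydroxylase gene Egln3 (-1.95, SE 0.30, adjusted p = 0.358) were lower. Next were Clu (1.73, SE 0.30, adjusted p = 0.622), Art1 (1.79, adjusted p = 0.771), Adamts13 (1.71) and Ush1c (1.41) on the higher side, and Gmds (-1.68, adjusted p = 0.645), Grip1 (-1.72, adjusted p = 0.771) and Gadd45g (-1.53, adjusted p = 0.793) on the lower. Cd44 stood at -2.28 (SE 0.54, adjusted p = 0.798), Nppb at -1.20 (SE 0.39, adjusted p = 0.952), Mki67 at 0.63 (SE 0.39) and Top2a at 0.71 (SE 0.41). As lists, the integrated stress response was lower at day 3 (0 of 33 over all genes, 2 lower adjusted over the list alone; list adjusted p = 1.57e-11, and adjusted p = 0.493 with an estimated correlation). Lower too were stress and hypertrophy genes (0 of 35, 7 lower adjusted over the list alone; list adjusted p = 2.15e-07) and YAP and TEAD targets (0 of 23, 4 lower adjusted over the list alone; list adjusted p = 1.22e-06), each at adjusted p = 0.493 with an estimated correlation. G2M genes were higher at day 3 as a list (0 of 51 over all genes and 0 adjusted over the list alone; list adjusted p = 7.89e-08, and adjusted p = 0.626 with an estimated correlation). Fibroblast markers were higher as a list as well (list adjusted p = 6.07e-05, and adjusted p = 0.626 with an estimated correlation). In cardiomyocyte-like nuclei edgeR called 0 genes (603 at unadjusted p under 0.05) and DESeq2 3. Leaving out libraries gave 11 (P1 MI day 1), 20 (P1 sham day 1), 72 (P1 MI day 3), 65 (P1 sham day 3), 9 (P8 MI day 1), 5 (P8 sham day 1), 65 (P8 MI day 3) and 59 calls (P8 sham day 3). In table nuclei edgeR called 0 genes (255 at unadjusted p under 0.05) and DESeq2 3. The smallest p-values were those of Gpnmb (4.55, SE 0.50), Clu (2.11, SE 0.46), Ucp2 (1.57), Stmn1 (1.75), Spp1 (5.38), Egln3 (-2.11), Uck2 (-1.57), Hbegf (-1.79) and Rpl21 (-1.79), each at adjusted p = 0.998.

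Between P1 and P8 sham hearts, cardiomyocyte-like nuclei gained the thyroid hormone receptor gene Thrb and ion channel genes and lost cell division and fetal growth genes. Thrb was 3.50 log2 higher at P8 (SE 0.29, adjusted p = 2.35e-04), at 275 CPM against 24.5 CPM. Slc35f2 (3.44, SE 0.35, adjusted p = 2.83e-04), the pacemaker channel gene Hcn2 (3.05, SE 0.51, adjusted p = 0.00314), Limch1 (2.97, SE 0.28), Prss41 (2.96), Pla2g10 (2.95), Itgb6 (2.85) and Scn3a (2.84, SE 0.28, adjusted p = 2.53e-04) were higher as well. Cited1 (-3.91, SE 0.40, adjusted p = 2.83e-04), Cep55 (-3.80, SE 0.41) and the kinetochore motor gene Cenpe (-3.71, SE 0.43, adjusted p = 5.17e-04) were lower. So were Bex4 (-3.62), Depdc1a (-3.59), Igf2bp1, which binds Igf2 mRNA (-3.58, SE 0.41, adjusted p = 4.24e-04), Ankle1 (-3.48) and mt-Atp8 (-3.45, SE 0.75, adjusted p = 0.0101). In contractile genes, Myh6 was higher (1.07, SE 0.21, adjusted p = 0.00637), while Tnni1 (-2.86, SE 0.39, adjusted p = 0.00108) and the atrial light chain genes Myl4 (-2.20) and Myl7 (-3.20) were lower at P8. Xirp2 was higher at P8 in sham (2.22, SE 0.22, adjusted p = 2.83e-04) and Nppa lower (-1.12, SE 0.29, adjusted p = 0.0208).

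Of 51 G2M genes, 50 were lower at P8 and 1 did not pass, with 51 lower adjusted over the list alone (Top2a -3.34, SE 0.28; Ube2c -3.41; Birc5 -2.92; Casc5 -2.95). The list had median -2.75, adjusted p = 2.68e-31, and adjusted p = 0.443 with an estimated correlation. Of 58 S phase genes, 35 were lower and 23 did not pass, with 1 higher and 40 lower adjusted over the list alone (Atad2 -2.44, Rrm2 -3.35, Mcm6 -2.22). They had list adjusted p = 1.46e-16, and adjusted p = 0.443 with an estimated correlation. Of 21 insulin-like growth factor and imprinted genes, 13 were lower and 8 did not pass, with 15 lower adjusted over the list alone (Igf2 -3.23, Mest -3.14, Igf2r -1.5). This list had adjusted p = 2.13e-10, and adjusted p = 0.211 with an estimated correlation. Of 41 calcium and ion channel genes, 16 were higher, 1 lower and 24 did not pass, with 18 higher and 1 lower adjusted over the list alone (among them Kcnd2, 1.44, and Hcn2). Ion channel genes had list adjusted p = 4.67e-06, and adjusted p = 0.443 with an estimated correlation. Mature contractile genes were split, 8 of 19 higher (among them Tcap, 1.09, and Myh6) and 1 lower (the ventricular light chain gene Myl3, -0.95), with 8 higher and 3 lower adjusted over the list alone. They had list adjusted p = 0.0310, and adjusted p = 0.530 with an estimated correlation. Of 77 oxidative phosphorylation genes, 50 were lower and 27 did not pass, with 1 higher and 57 lower adjusted over the list alone (list adjusted p = 2.41e-19, and adjusted p = 0.473 with an estimated correlation). Of 61 ribosomal protein genes, 36 were lower and 1 higher (2 higher and 42 lower adjusted over the list alone; list adjusted p = 2.10e-14, and adjusted p = 0.485 with an estimated correlation). Of 13 genes encoded by mitochondrial DNA, 12 were lower (13 adjusted over the list alone; list adjusted p = 3.32e-11, and adjusted p = 0.443 with an estimated correlation). Mitochondrial UMI shares were 23.9% and 18.8% in P1 sham and 4.07% and 3.59% in P8 sham. In cardiomyocyte-like nuclei edgeR called 2321 genes, 1019 higher and 1302 lower at P8. Leaving out P1 sham day 3, P8 sham day 1 or P8 sham day 3 gave 570, 1318 and 613. In table nuclei it called 4618, 1795 higher and 2823 lower, led by Slc35f2 (4.25), Thrb (3.70), Dlk1 (-6.04, SE 0.53, adjusted p = 0.00290) and Mest (-3.92). Leaving out P1 sham day 1, P1 sham day 3, P8 sham day 1 or P8 sham day 3 gave 27, 2513, 456 and 32 calls. Fibroblast-like nuclei were 24.6% and 21.2% of P1 sham but 5.09% and 5.02% of P8 sham.

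Set beside the difference between sham ages, the P8 MI effect shared genes in both directions in cardiomyocyte-like nuclei. Of the genes that fell after P8 MI, 197 were also higher in P8 than P1 sham (76.2 expected) and 109 lower (97.3 expected). Of those that rose after P8 MI, 143 were lower in P8 than P1 sham (85.0 expected) and 57 higher (66.5 expected). These fits use the same P8 sham libraries. Across 13576 genes, which are not independent replicates, r between the effects was -0.227 with covariance -0.0957, against -0.455 and -0.0499 in simulated sets with no effect. With no shared library, P8 MI at day 3 against age at day 1 gave r = -0.254, and P8 MI at day 1 against age at day 3 gave r = -0.0378. The P1 MI effect had the other sign: r = 0.107 at day 3 against age at day 1 and 0.1185 at day 1 against age at day 3. With shared P1 shams its r was 0.358, against 0.579 in simulated sets.

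Nuclei holding G2M transcripts were more frequent at P1 than at P8 among cardiomyocyte-like nuclei, while 4 pairs are too few for a difference between MI and sham to pass the threshold. Their share there was 8.57% [6.97 to 10.4] in P1 MI day 1 and 10.2% [7.92 to 12.9] in its sham, 25.5% [22.9 to 28.3] in P1 MI day 3 and 24.9% [22.6 to 27.3] in its sham. At P8 it was 1.93% [1.41 to 2.57] and 2.11% [1.59 to 2.74] at day 1, and 4.0% [3.23 to 4.90] and 2.94% [2.22 to 3.79] at day 3, for MI and sham. The mean difference over 4 pairs was -0.0252 points (exact sign flip p = 1, higher in 2 of 4 pairs, range -1.62 to 1.07). Without thinning it was 4.69 points (exact p = 0.13, the smallest 4 pairs can give; higher in 4 of 4 pairs), thinned to 500 UMIs 1.74 points (exact p = 0.25), and with at least 3 genes 0.299 points. With at least 1 gene it was -1.55 points (higher in 1 of 4 pairs) and over all barcodes -0.208 points. In table nuclei the mean difference was 3.97 points (exact p = 0.375, higher in 3 of 4 pairs, range -3.06 to 9.99). There it was 11.8 points without thinning (higher in 4 of 4 pairs), 2.82 thinned to 500 UMIs, 2.42 with at least 3 genes, 5.13 with at least 1 gene and 4.01 over all barcodes. Without thinning, deeper nuclei show more of these genes, and MI nuclei were deeper in each pair. Median UMIs per table nucleus at P1 were 2580 in MI and 1991 in sham at day 1, and 2884.5 and 1211 at day 3. At P8 they were 1369 and 1165, and 1725 and 1067. The values without thinning thus cannot be told apart from depth. Shares in table nuclei were 13.6% and 16.7% at P1 day 1, 31.2% and 23.2% at P1 day 3, and 3.69% and 2.74% at P8 day 1, for MI and sham. At P8 day 3 they were 13.8% [12.8 to 14.9] and 3.82% [3.05 to 4.71]. In fibroblast-like nuclei of P8 day 3 the share was 29.2% [26.1 to 32.5] in MI and 8.18% [3.81 to 15] in sham, and in macrophage-like nuclei 28.0% [23.8 to 32.4] and 13.9% [4.67 to 29.5]. The values without thinning at P1 day 1 in cardiomyocyte-like nuclei were 18.1% and 17.5%. Nuclei too shallow to be thinned, and left out, were 730 in P1 sham day 3, 625 in P8 MI day 1, 1144 in P8 sham day 1, 219 in P8 MI day 3 and 1451 in P8 sham day 3, and 0 in the other cardiomyocyte-like libraries. The share that free RNA alone would give was not measured here, and the other classes, which held more of these nuclei than cardiomyocyte-like ones, give no zero level for it.

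Within single pairs of cardiomyocyte-like nuclei, the intervals hold counting error alone, and ratios were not compared between pairs. At P1 day 1, Thbs1 had 72 UMIs in MI and 0 in sham, a ratio with an exact 95% lower limit of 7.53. Col12a1 was 30.5-fold higher [5.31 to 1220], Cd44 21.3-fold [8.19 to 78.8] and Xirp2 19.6-fold [14.4 to 27.5]. The ratio of Lrrc4c was 0.133 [0.0966 to 0.180] and that of the collagen-binding gene Lum 0.179 [0.112 to 0.282]. At P1 day 3, Spp1 was 60.3-fold higher [23.3 to 223], Xirp2 13-fold [10.8 to 15.7], Nppa 10.5-fold [9.74 to 11.4] and Tpm2 7.66-fold [5.54 to 10.9]. At P8 day 1, Epha2 (73 UMIs), Ahnak2 (64) and Snhg11 (56) had 0 UMIs in sham, with lower limits of 19.3, 16.9 and 14.7, and Eno2 was 51.0-fold higher [21.6 to 158]. The interferon-induced GTPase genes Iigp1 and Irgm2 had ratios of 0.00918 [2.30e-04 to 0.0522] and 0.0351 [0.00940 to 0.0924]. At P8 day 3, Sprr1a had 97 UMIs in MI and Ccl9 59, with 0 in sham and lower limits of 21.4 and 12.9, Spp1 was 210.1-fold higher, and Tacr3 had a ratio of 0.0686 [0.0417 to 0.107].

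On GRCm38, Xirp2 (ENSMUSG00000027022) lies on chromosome 2 from 67446002 to 67526614, Nppa (ENSMUSG00000041616) on chromosome 4 from 148000722 to 148002079, and Cd44 (ENSMUSG00000005087) on chromosome 2 from 102811141 to 102901665. Eno2 (ENSMUSG00000004267) lies on chromosome 6 from 124760053 to 124769673 and Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050.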

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

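Of the tests here, those of captured RNA and of doublets in the mixed cluster were chosen only after its values were seen, and each result on cardiomyocyte-like nuclei uses a set chosen after seeing the data. Groups held 1 library each, so no test asked whether a library lies far from its group.

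The MI effect differed between P8 and P1, by the test of the difference itself, for 336 genes in table nuclei (2 with additive age and day, 81 without mitochondrial, ribosomal and haemoglobin genes and Malat1) and for 12 in cardiomyocyte-like nuclei (2 with equal nuclei and totals; 0 in edgeR under 5% mitochondrial UMIs, 1027 at unadjusted p under 0.05). Leaving out 1 library gave 5 to 2645 and 20 to 159. In cardiomyocyte-like nuclei the log2 difference was 3.66 for Mfap5, 2.52 for Ankrd6, 2.33 for Ptprg, -3.38 for Tacr3, -3.31 for Scn3a, -2.74 for Mrps27 and -2.72 for Caln1. It was -2.37 for Scaf1, -2.34 for Tmprss11d and -2.11 for Lrrc48. Whether low levels in P1 sham limited the falls at P1 was not tested.

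Nuclei that stand outside the cardiomyocyte-like comparisons showed a signal in both P1 MI libraries: the mixed cluster held 27.3% of table nuclei in P1 MI day 1 and 24.3% in P1 MI day 3, against 1.87% and 0.18% in their shams. Across genes, the ratio of the cluster to cardiomyocyte-like nuclei of the same library falls with gene length (Spearman correlations -0.560 and -0.555). A loss of long, intron-rich nuclear transcripts would give this. It was the outcome set beforehand to count against a cardiomyocyte state of P1 infarcts and nothing else. It cannot decide, since no other cluster was measured in this way and a state with higher short genes would give it too. Doublets of a cardiomyocyte nucleus with another nucleus are argued against by Malat1, a nuclear transcript: it took 4.40% and 3.63% of non-mitochondrial UMIs in the cluster, below the 5.29% and 5.88% of the lowest named class and the 16.5% and 17.2% of cardiomyocyte-like nuclei. Captured cytoplasmic or free RNA is a candidate explanation that the values allow: markers of 4 of the 6 other cell types had a median ratio above 1.5 over cardiomyocyte-like nuclei in both P1 MI libraries (fibroblast 2.76 and 5.15, endothelial 2.90 and 3.49, mural 1.65 and 3.01, macrophage 1.61 and 2.21), while endocardial (1.13 and 1.38) and epicardial markers (1.34 and 1.35) did not. A change of P1 cardiomyocytes after MI, alone or together with such RNA, stays open, as do atrial cardiomyocytes mixed with it. The mixtures were not tested. Among the top 10 genes of the cluster, Nppa, Myl4 and Myl7 are atrial markers. Acta1, Acta2, Actc1, Myl4 and Myl7 are on the immature contractile list, and Nppa, Acta1, Hspb1 and Des on the stress and hypertrophy list.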

How the results depend on the processing

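Of the settings here, those on clusters, mitochondrial share, doublet scores and fry, and each value on cardiomyocyte-like nuclei, were chosen only after the results were seen. With 1 library per condition, each count rests on few degrees of freedom, and where 1 library is left out its partner adds nothing to the pair. Without a P8 library, the residual spread of the P1 test comes from the P1 pairs alone, and the reverse holds for P8. On simulated data the test recovered 58% and 72% of 4-fold changes at P1 in table and cardiomyocyte-like nuclei and 51% and 85% at P8, so 4-fold changes can be missed in either set. The simulated spread came from the fit with a single MI effect, so these rates need not be those of the P1 and P8 tests on the real counts. The cause of each change below was not tested, except that the stricter filter tests fewer genes and equalised libraries hold fewer counts. Of 1946 values of genes under the naming rule in cardiomyocyte-like nuclei under other settings, 1804 kept direction and call, 86 lost the call, 27 gained it and 29 without a call changed sign. With libraries left out these counts were 1067, 49, 53 and 55 of 1224. In table nuclei they were 1127, 67, 35 and 10 of 1239, and 1026, 103, 52 and 67 of 1248. No called gene reversed.

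Values below are numbers of genes called in table nuclei, where edgeR gave 9 over 4 pairs, 27 at P1, 2459 at P8, 336 for the difference between ages, 0 for that between days and 4618 for sham age. Without a count filter there were 139 over 4 pairs, 859 at P1 and 1556 for the age difference. With at least 50 counts in 4 libraries there were 10 at P1 and 47 for the age difference. DESeq2 called 914 over 4 pairs, 167 at P1, 578 for the age difference and 3 for the day difference. RLE gave 42 at P1, all barcodes 156 and equal nuclei 153 for the age difference. Without mitochondrial, ribosomal and haemoglobin genes and Malat1 there were 16 at P1 (62.5% higher, against 48.2%) and 81 for the age difference. Additive age and day gave 18 over 4 pairs, 6 at P1 and 2 for the age difference, and sham libraries alone 7213 for age. The P8 count stayed within 1.5 times under each of these settings, from 1873 to 3534 calls. Leaving out 1 library gave 0 to 237 calls over 4 pairs, 2 to 1728 at P1, 1791 to 3386 at P8, 5 to 2645 for the age difference, 0 in each case for the day difference and 27 to 6744 for sham age. The 0 over 4 pairs (edgeR; DESeq2 914 with each library kept) came without P1 MI day 1, P1 sham day 1, P1 MI day 3, P1 sham day 3, P8 MI day 1 or P8 sham day 1, with 3035, 3065, 2884, 2876, 1405 and 1398 genes at unadjusted p under 0.05. The 2 and 5 came without P1 sham day 1 and the 27 without P1 sham day 1. The 1728 and 2645 came without P8 sham day 1.

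In cardiomyocyte-like nuclei edgeR gave 2539 over 4 pairs, 35 at P1, 1901 at P8, 12 for the age difference, 0 for the day difference (603 at unadjusted p under 0.05) and 2321 for sham age. Equal nuclei and totals gave 1168, 66, 547 and 2 for the first 4 and 1198 for sham age. Without a count filter there were 1039 at P1, 244 for the age difference and 24 for the day difference, and with the stricter filter 10 at P1, 1174 at P8 and 5 for the age difference. DESeq2 called 212 at P1, 838 at P8, 23 for the age difference and 3 for the day difference. At P1, RLE gave 193 (55.4% higher, against 74.3%), all barcodes 204, the gene classes left out 210 (52.4% higher) and additive age and day 237. At P1, the count was 1443 with the mixed cluster, 119 with the mixed and mitochondrial RNA-rich clusters, 11 in nuclei under 5% mitochondrial UMIs, 20 without the cycling cluster and 132 without the highest doublet scores. For the age difference, it was 26 with the mixed cluster and 0 (edgeR, 1027 at unadjusted p under 0.05) under 5% mitochondrial UMIs, and for sham age 4119 with the mixed and mitochondrial RNA-rich clusters. Leaving out 1 library gave 377 to 2687 over 4 pairs, 114 to 805 at P1, 365 to 2941 at P8, 20 to 159 for the age difference, 5 to 72 for the day difference and 570 to 2595 for sham age. The lowest of these came without P8 MI day 1, P1 sham day 3, P8 MI day 1, P1 sham day 3, P8 sham day 1 and P1 sham day 3.

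The G2M difference between MI and sham in cardiomyocyte-like nuclei, -0.0252 points, turned positive when thinned to 500 UMIs (1.74), not thinned (4.69) or with at least 3 genes (0.299), and stayed negative with at least 1 gene (-1.55) and over all barcodes (-0.208). The value not thinned also holds the greater depth of MI nuclei. Of 234 list tests each, 132 passed in table and 81 in cardiomyocyte-like nuclei at the preset correlation, 0 and 0 with an estimated correlation and 16 and 8 with fry.

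In other classes, MI over 4 pairs gave 147 calls in fibroblast-like, 47 in macrophage-like and 12 in endothelial-like nuclei. Without a filter these were 754, 214 and 199, and with the stricter filter 12, 0 (edgeR, 197 at unadjusted p under 0.05; DESeq2 with the usual filter 62) and 4; DESeq2 gave 35 in endothelial-like nuclei. Leaving out P1 MI day 1, P1 sham day 1, P1 MI day 3, P1 sham day 3, P8 MI day 1, P8 sham day 1, P8 MI day 3 or P8 sham day 3 gave 25, 27, 45, 30, 11, 11, 1296 and 1331 in fibroblast-like nuclei. In the same order it gave 102, 109, 1, 1, 5, 5, 708 and 694 in macrophage-like and 9, 8, 31, 41, 4, 4, 219 and 221 in endothelial-like nuclei.

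Of 35 splits of the 8 libraries into 4 and 4, 32 could be fitted. For table nuclei 3 of 32 gave at least the 9 genes of MI against sham, the highest other 722. The splits with 722 part P8 by surgery and leave both P1 pairs whole, so with the pair as block they estimate the MI effect at P8. For cardiomyocyte-like nuclei 1 of 32, the real one with 2539 genes, reached that count, the highest other being 32. With the pair as block, only the 8 splits that part each pair exchange MI and sham, and these are too few for a share under 0.05. Among them the real split gave 9 and 2539 genes and the highest other 0 and 0 (edgeR).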

Other observations

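The tests of cardiac RNA in other cell types were chosen only after their values were seen, as were the minimum of 2-fold over other classes and 30 CPM for a cardiomyocyte-specific gene and the set of cardiomyocyte-like nuclei used throughout. So were the tests of shared shams and of gene length and level for each day apart; the test of a shift toward P1 was written beforehand.

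Some genes of cell survival, protein folding and fetal growth also rose over the 4 pairs in cardiomyocyte-like nuclei, while most members of these lists did not pass. Of 25 p53 and apoptosis genes, 8 rose and 1 fell, with 16 not passing and 8 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0403, and adjusted p = 0.759 with an estimated correlation). The risers did not share 1 role: Bcl2 (2.14, SE 0.18, adjusted p = 8.25e-04) and Mcl1 (0.75, adjusted p = 0.0204) are known to block apoptosis, Bnip3 (1.15, adjusted p = 0.00962) to promote mitophagy and death, and Ccng1, a p53 target, fell (-0.86, adjusted p = 0.0124). Among 18 heat shock genes, 4 rose and 14 did not pass, with 4 higher adjusted over the list alone: Hspa1a (4.01, SE 0.67), Hsp90aa1 (0.92), Hspa4l (0.75) and Hspb8 (0.77; list adjusted p = 0.286). Of 21 insulin-like growth factor and imprinted genes, 5 rose, among them Hmga2 (2.53, SE 0.50, adjusted p = 0.0116), Igf2bp2 (1.57), Peg3 (1.80) and Meg3 (1.48), with 5 higher adjusted over the list alone (list adjusted p = 0.0413, and adjusted p = 0.759 with an estimated correlation). In 41 calcium and ion channel genes, 8 rose, such as the sodium-calcium exchanger gene Slc8a1 (1.16, SE 0.16, adjusted p = 0.00352), 3 fell and 30 did not pass (11 higher and 5 lower adjusted over the list alone; list adjusted p = 0.339).

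Between sham ages, metabolism and redox genes moved apart within their lists in cardiomyocyte-like nuclei. Slc16a3, a lactate exporter (-4.0, SE 0.70, adjusted p = 0.00364), Tpi1 (-1.27, SE 0.18) and Ldha (-1.12, SE 0.19) were lower at P8 and Pfkm, the muscle phosphofructokinase (1.0, SE 0.19), higher. Of 28 glycolysis genes, 2 were higher, 5 lower and 21 did not pass, with 3 and 9 adjusted over the list alone (list adjusted p = 0.148). Of 28 hypoxia genes, 4 were higher (Vegfa 2.37, Epas1 1.45) and 4 lower (Hif3a -2.05), with 6 and 4 adjusted over the list alone. The hypoxia list had a median of -0.06 and a mean of -0.03, while its test leaned higher (adjusted p = 0.736). Among 28 antioxidant genes, 9 were lower (Txn1 -1.86, Gclm -1.34, Prdx1 -1.31) and 2 higher, with 10 and 2 adjusted over the list alone (list adjusted p = 0.0347, and adjusted p = 0.473 with an estimated correlation).

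A few transcripts of cardiomyocytes were also higher after MI in fibroblast-like, macrophage-like and endothelial-like nuclei: Xirp2 by 4.12, 3.73 and 3.92 (edgeR adjusted p = 0.00273, 0.00896 and 4.76e-04) and Nppa by 4.22, 3.06 and 3.43 (adjusted p = 9.43e-04, 0.0785 and 4.76e-04), where Nppa did not pass in macrophage-like nuclei and Ttn and Myh6 passed in 0 of the 3 classes. Across 213, 193 and 194 cardiomyocyte-specific genes, their MI changes and those of cardiomyocyte-like nuclei had Spearman correlations between 0.814 and 0.904. Free cardiomyocyte RNA and expression of these genes by the other types cannot be told apart by them, because genes at least as high in the other class were correlated as well (0.628, 0.577 and 0.641). The reverse, RNA of other types in cardiomyocyte-like nuclei (Spp1, Ccl2 or Ptprc, for example), was not tested and stays open.

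Of 1019 genes higher in P8 than in P1 sham, 197 were called lower after MI at P8 (76.2 expected if independent) and 57 higher (66.5 expected). These calls share the P8 sham libraries. Across genes, the relation had r = -0.227 and covariance -0.0957, against -0.455 and -0.0499 in simulated sets with no effect. For MI at day 3, the shared P8 sham libraries and gene length with expression level are each argued against as the whole cause, since from pairs with no common library the correlation was -0.254, and -0.274 with length and level regressed out. For MI at day 1 it was -0.0378, so the shared shams are a candidate explanation there, and length and level cannot be told apart from the relation because -0.0732 with both regressed out lies between the bounds. A shift toward the P1 profile in both gene sets and on both days is argued against: genes lower in P8 sham had a median MI change of 0.30 at day 3 but -0.27 at day 1. Genes higher in P8 sham moved as such a shift predicts, with medians of -0.28 at day 3 and -0.16 at day 1, so a shift of a part of the profile stays open. RNA of other cell types in cardiomyocyte-like nuclei, not tested here, stays open as well. Fibroblast-like shares were 24.6% in P1 sham day 1 and 5.09% in P8 sham day 1. At P8 they were 18.5% in MI and 5.02% in sham at day 3, against 4.87% and 5.09% at day 1.

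A further 1434 barcodes lay outside the deposited table, of which 446 (31.1%) were cardiomyocyte-like and 424 (29.6%) rich in mitochondrial RNA. Sex-linked transcripts of these mice differed between libraries of cardiomyocyte-like nuclei: Xist was at 4568 and 4412 CPM in P8 MI (day 1, day 3) and 3066 and 3322 CPM in P8 sham, and the Y-linked gene Eif2s3y at 13.8 and 27.3 CPM in P8 MI and 67.9 and 71.7 CPM in P8 sham. At P1, Xist was at 1863 and 2234 CPM in MI and 3386 and 2455 CPM in sham. Eif2s3y there was at 78.7 and 56.9 CPM in MI and 46.0 and 86.8 CPM in sham, so at P1 day 3 both transcripts were lower in MI. The mix of sexes per library is not given in the sources used here. At P8 these transcripts differed along with surgery. A part of the P8 MI effect, or of its difference from P1, that comes from the mix of sexes cannot be told apart here and was not tested.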
